A study of Mus musculus with 12 samples.

How the data were processed

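The deposited values were FPKM (fragments per kilobase of exon, scaled by library total) per gene, rounded to 2 decimals, in 1 table of 52105 genes and 12 libraries, per the file headers. The authors extracted total RNA from deciduae with TRIzol and prepared libraries from it with an Illumina TruSeq RNA kit, per the labels' protocols. The submitters' processing notes name the aligner STAR and the mouse genome build mm10. The version of STAR, the program that counted reads and the gene annotation were not given in the sources used here. Of the 52105 genes, 19393 were listed at 0 in all 12 libraries. Gene positions and exon lengths came from the GENCODE M21 annotation of the same build, and 101 symbols of the table had several gene identifiers there. Reads shared by near-identical genes were counted in a way that was not given, so values of the Prl3d, Prl2c, granzyme D to G, Psg, haemoglobin and immunoglobulin genes and of processed pseudogenes are uncertain. Values of overlapping and antisense genes are uncertain for the same reason, since the use of strand was not given.

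FPKM values are not counts, so the main fit used no count model. The total by which FPKM had been divided was inferred from low values. In each library, 930 to 1091 values of genes with an exon length of 150 to 600 bases, an FPKM of at least 0.08 and at most 6.5 reads were compared with whole numbers of reads. A value counted as whole when it lay within the rounding of 0.005 FPKM plus 0.02 reads. The total that brought these values closest to whole numbers was taken for each library. At that total 99.4% to 100% of the values were whole, against 15.8% to 18.8% by chance. Summed over genes, the rebuilt reads came to 82.6% to 107.5% of that total, so it need not be the sequencing depth. Whether the units were reads or fragments was not given.

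Values were computed from the deposited FPKM as log2(FPKM + 1). Fold changes are on that scale, which understates the change of genes with low FPKM. Genes with an FPKM of at least 1 in at least 3 of the 12 libraries were tested, which left 12963 genes. limma 3.58.1 in R 4.3.3 fitted 4 group means, 1 for each day and genotype, with a variance trend over mean expression. Its moderated test was two-sided. P-values were adjusted over all genes tested by the method of Benjamini and Hochberg, and a gene was called at an adjusted p under 0.05. The difference between days was the DTA effect at day 8 minus the DTA effect at day 6.5. No table named a batch. The titles of replicate 3 were written in another form than those of replicates 1 and 2, so fits without replicate 3 and with a term for replicate 3 were made. The labels call the replicates biological but did not state whether each was a single animal or a pool, so p-values measure the spread between these libraries. The fit pooled the spread of each gene over the 4 groups. That pooled spread can be too small for the D6.5 DTA libraries, which differed more from each other than the D6.5 WT libraries did.

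The 28 gene lists were fixed before the data were examined. They covered giant cell trophoblast, other trophoblast, visceral endoderm and yolk sac, embryonic erythroid genes, adult blood, Y-linked genes, decidual stroma, progesterone receptor and hedgehog targets, endothelium and angiogenic factors. Further lists covered natural killer cells, macrophages with antigen presentation, neutrophils, T and B lymphocytes, interferon response, inflammatory cytokines, myometrium, uterine epithelium and proliferation. The remaining lists covered p53 and apoptosis, glycolysis and hypoxia, the unfolded protein response, extracellular matrix, retinoic acid, Wnt and BMP signalling, steroid metabolism, insulin-like growth factors and mitochondrially encoded genes. Lists with at least 3 tested members (25 of 28) were compared with all other tested genes by camera in limma, with a preset correlation of 0.01, and again with a correlation estimated per list. Adjusted p-values of lists were adjusted over the 25 lists. Counts adjusted over the list alone used the p-values of the members of that list only.

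Named genes followed a rule fixed before the data were examined. For each comparison of DTA with WT, Prl3d1 came first. Next came the 8 largest rises and the 8 largest falls among called genes whose 3 DTA libraries all lay on the same side of the 3 WT libraries, with a mean FPKM of at least 5 in the higher group. Symbols made of Gm or LOC and digits, symbols ending in Rik and accession-like symbols were left out. Up to 4 members of each described list with the smallest p followed. Prl8a2, Bmp2, Wnt4, Hand2, Hoxa10, Pgr, Vegfa, Kdr, Prf1 and Afp were given whatever their p. For the change between days in WT the 6 largest each way and the list members were named. For the difference of the DTA effect the 5 largest each way were named without the condition on separated libraries, with Wnt4, which was called there and is among the genes always given.

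The fits were tested on simulated data with known changes, drawn with independent normal noise and the same spread per gene in every group. At day 6.5, 90% of 100 genes changed by a log2 fold change of 1 and 99% of 100 genes changed by 2 were recovered among 12617 genes, and 4.37% of calls were not changed genes. At day 8 the shares were 86% and 100% among 12621 genes, with 6.73% of calls not changed. For the difference between days they were 70% and 92% among 12612 genes, with 3.57% of calls not changed. The real D6.5 DTA libraries differed more from each other than the D6.5 WT libraries did, so these shares need not hold for the real data.

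Alternatives changed 1 choice at a time: a pseudocount of 0.1 or 5, no filter or a filter of FPKM of at least 5, scaling to an equal sum (TPM), by the median of ratios to the geometric mean or by quantiles, limma without the trend or with robust estimation, weights per library, a replicate block, a term for replicate 3, fits of only the groups compared, and fits without each library or each replicate number. limma voom on reads rebuilt from FPKM, exon length and the inferred total, and 1 block across both days, were added after the data were seen. Tallies of alternatives for single lists leave out camera with an estimated correlation, whose result is given beside each called list. Every labelled library was used, and no column of the table was left without a library.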

Results

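RNA was sequenced from mouse decidua, the maternal tissue that forms from the endometrium around an implanting embryo, at days 6.5 and 8 of pregnancy. Myometrium and embryonic tissue had been removed. The DTA pregnancies carried a Cre recombinase driven by Prl3d1, a placental lactogen gene of trophoblast giant cells, and a Rosa26 allele that makes diphtheria toxin A once Cre has acted, so that primary trophoblast giant cells are ablated. The other pregnancies were wild type (WT). The 12 libraries formed 4 groups of 3, named D6.5 WT, D6.5 DTA, D8 WT and D8 DTA. The design text speaks of fewer replicates than the 3 per group that the labels list, and all 3 were used. Positions are those of the mm10 build.

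The deposited values were FPKM, and the totals by which they had been divided were inferred from the steps between low values. These totals ranged from 31.25 M to 38.89 M reads or fragments (M for mega) across the 12 libraries. They were 37.12, 35.56 and 35.82 M in D6.5 WT, 37.34, 38.89 and 32.61 M in D6.5 DTA, 31.25, 31.75 and 32 M in D8 WT, and 32.54, 31.47 and 34.43 M in D8 DTA. Reads rebuilt from them and summed over genes came to 90.4% to 93.8% of the total in D6.5 WT and to 105.3% to 107.5% in D8 WT. The totals therefore need not be the sequencing depth. Between 11949 and 12594 genes per library had an FPKM of at least 1. The 10 genes with the highest FPKM took 10.2% to 21.3% of the summed FPKM, and mitochondrially encoded genes took 6.8% to 13.2%. Libraries of the same group correlated across genes with r of 0.9507 to 0.9956 on the log2(FPKM + 1) scale. Values of r were 0.9507, 0.9662 and 0.976 among the D6.5 DTA libraries, against 0.9893 to 0.9933 among the D6.5 WT libraries. They were 0.9706, 0.9792 and 0.9917 among the D8 DTA libraries, against 0.9919 to 0.9956 among the D8 WT libraries. The first principal component, with 59.8% of the variance, parted the days. D6.5 DTA replicate 1 stood apart on the second component at 35.3, with the other D6.5 DTA libraries at 2.91 and 2.61. D8 DTA replicate 3 lay at 8.0 on the first component, with the other D8 DTA libraries at 24.7 and 33.1. Values below are means ± SD of 3 libraries, log2 fold changes are on the log2(FPKM + 1) scale, and adjusted p-values are from limma. An exact permutation test of 3 libraries against 3 cannot give a p below 0.1.

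The driver gene showed whether the labels match the ablation. Prl3d1 (ENSMUSG00000057170.6, chromosome 13: 27094190-27100258) was lower in every DTA library than in every WT library at both days. At day 6.5 it was listed at 7.61, 29.2 and 9.16 FPKM in WT and at 0.34, 0 and 0.03 in DTA, a log2 fold change of −3.63 (SE 0.38, adjusted p = 0.000598). At day 8 it was listed at 24.06, 12.94 and 18.2 FPKM in WT and at 0.07, 0.4 and 0.07 in DTA, a log2 fold change of −4.01 (SE 0.38, adjusted p = 0.000352). Its near-identical neighbour Prl3d2 fell as well, from 6.94 to 0.0433 FPKM at day 6.5 (log2 fold change −2.71, adjusted p = 0.00203) and from 3.93 to 0.167 FPKM at day 8 (−2.04, adjusted p = 0.0228). Reads of Prl3d1, Prl3d2 and Prl3d3 may have been shared. Decidua is maternal, and the labels gave WT or DTA per library but not the genotype of the mother. The Rosa26 transcript was at 0.06 to 0.24 FPKM in D8 DTA, against 3.65 FPKM in D8 WT, and at 0.30 to 4.06 FPKM in D6.5 DTA. The maternal tissue thus differed at this locus between D8 DTA and D8 WT and among the D6.5 DTA libraries. Mothers may have differed in Rosa26 genotype in the same way and between days. Neither a DTA effect nor its difference between days can therefore be assigned to the ablation alone.

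Of the 8 tested members of the giant cell trophoblast list, 3 fell at day 6.5 (Prl3d1, Prl3d2 and Prl3d3) and 5 did not pass, with the same counts adjusted over the list alone. The list median was −0.83 (camera adjusted p = 0.000598), and the call was lost with an estimated correlation (adjusted p = 0.385). Without single libraries that median ran from −1.67 to −0.39, and it was −0.15 without a filter, −2.39 with only the groups compared and −3.32 with limma voom, so its size was not settled. At day 8, 4 of the 8 fell, among them Prl5a1 and Prl7a1, 5 when adjusted over the list alone, and none rose. The median at day 8 was −1.38 (camera adjusted p = 2.68e-06, and adjusted p = 0.194 with an estimated correlation), and −0.50, −0.59 and −0.77 without D8 WT replicate 1, 2 or 3. It was −0.27 without a filter, −0.42 and −3.37 with a pseudocount of 5 and 0.1, −2.40 with TPM and −3.93 with limma voom. Prl5a1 averaged 2.05 FPKM in D8 WT and was listed at 0 in all 3 D8 DTA libraries (adjusted p = 0.000207). Prl7a1 averaged 3.09 FPKM in D8 WT and 0.127 in D8 DTA (adjusted p = 0.00353).

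Cts7, a cathepsin of trophoblast, was the only called member among the 6 tested genes of the other trophoblast list at either day. It averaged 3.02 FPKM in D6.5 WT and was listed at 0 in all 3 D6.5 DTA libraries (adjusted p = 0.00139), and it fell from 6.91 to 0.00667 FPKM at day 8 (log2 fold change −2.95, adjusted p = 9.76e-05). The median of this list was −0.35 at day 6.5 (camera adjusted p = 0.0302, and adjusted p = 0.385 with an estimated correlation) and −0.42 at day 8 (camera adjusted p = 0.0576). Adjusted over the list alone, 1 gene was lower at day 6.5, and 1 was higher and 2 were lower at day 8. The pregnancy-specific glycoprotein gene Psg22 fell at day 8 from 5.73 ± 1.27 to 0.0433 ± 0.038 FPKM (log2 fold change −2.67, adjusted p = 1.62e-05).

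**Figure D1:**
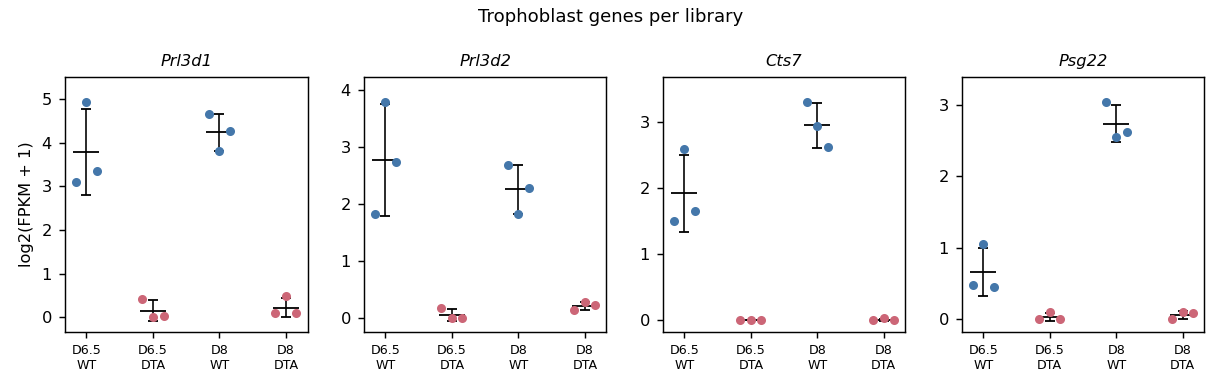
Expression of Prl3d1, Prl3d2, Cts7 and Psg22 as log2(FPKM + 1) in each of the 12 libraries, with points for libraries and bars for the mean ± SD of the 3 libraries of a group. Prl3d1 averaged 15.3 FPKM in D6.5 WT and 0.123 in D6.5 DTA, and 18.4 FPKM in D8 WT and 0.18 in D8 DTA.

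Beside the trophoblast transcripts above, Y-linked, embryonic haemoglobin and Afp transcripts were near 0. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty averaged at most 0.0233 FPKM in any group, and embryonic haemoglobin genes at most 0.02 FPKM, so neither list had a member to test. Afp, a yolk sac gene, averaged 0.0867, 0.05, 0.0467 and 0.06 FPKM in D6.5 WT, D6.5 DTA, D8 WT and D8 DTA. In the visceral endoderm and yolk sac list 3 members were tested. Of these, Spink1 rose at day 6.5 from 25.1 to 91.7 FPKM (log2 fold change 1.98, adjusted p = 0.0436), Rbp4 and Rhox5 did not pass, and adjusted over the list alone 1 was higher and 1 lower. The list did not pass at day 6.5 (median 0.35, camera adjusted p = 0.681) or day 8 (median −0.03, camera adjusted p = 0.953). The 4 tested genes of adult blood, haemoglobins of the mother's red cells, did not pass at day 6.5 (median 0.08, camera adjusted p = 0.861) or day 8 (median −0.27, camera adjusted p = 0.430).

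The comparison at day 6.5 addressed how the decidua differs when primary giant cells are ablated. By camera the lists of decidual, endothelial, natural killer and interferon-response genes were lower in DTA deciduae and that of macrophage genes was higher. With an estimated correlation none of these passed (adjusted p = 0.0902, 0.385, 0.516, 0.385 and 0.132). The decidual prolactin Prl8a2 (ENSMUSG00000018259.13, chromosome 13: 27345673-27354216) fell from 1218 ± 93.2 FPKM in WT to 339.5 ± 213 FPKM in DTA (n = 3 each, log2 fold change −2.05, SE 0.41, adjusted p = 0.0131). Wnt4, a signal needed for stromal cells to become decidual cells, fell from 102 to 47.8 FPKM (log2 fold change −1.06, adjusted p = 0.00368), and Bmp2, another such signal, fell from 299 to 150 FPKM (−1.05, adjusted p = 0.0107). The antibody light chain gene Igkc rose from 11.9 ± 15.7 to 135 ± 11 FPKM (log2 fold change 4.17, adjusted p = 0.0119). Of 12963 genes tested, 435 were higher and 719 lower in DTA, with 107 and 102 of these changed at least 2-fold. Fitted to the day 6.5 libraries alone, with fewer libraries behind the spread, limma called 411 genes in place of these 1154. The share of higher genes, 37.7% of the 1154 calls, was 53.9% with limma voom (691 higher) and 49.5% without a filter. The balance of rises and falls thus depended on the processing.

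Among the largest rises of single genes at day 6.5 were antibody genes and pseudogenes, for which no list was tested. Jchain, which joins secreted antibodies, rose from 0.817 to 13.7 FPKM (log2 fold change 3.10, adjusted p = 0.00044), and Igha, the heavy chain of IgA, from 4.67 to 32.9 FPKM (3.10, adjusted p = 0.0214). The variable segments Igkv5-39 and Igkv8-21 rose by log2 fold changes of 3.23 and 3.03 (adjusted p = 0.000433 and 0.00195). Reads of such genes may be shared within the family. Of the T and B lymphocyte list only Ighm was tested, and it rose by 0.48 (adjusted p = 0.0352). The pseudogenes Vcp-rs and Atp6v0c-ps2 rose from 3 to 63.1 FPKM and from 2.97 to 59.0 FPKM (log2 fold changes 3.94 and 3.77, adjusted p = 1.46e-05 and 0.000282), with reads that may belong to their parent genes. Mmp7, a matrix metalloproteinase, averaged 1.25 FPKM in WT and 19.4 ± 21.4 FPKM in DTA (2.85, adjusted p = 0.016), with DTA replicate 1 at 43.99 FPKM. The largest falls by the naming rule, besides Prl3d1, Prl3d2 and Prl8a2, were in Stac2 (27.9 ± 1.5 to 4.93 ± 1.29 FPKM, log2 fold change −2.31, adjusted p = 0.00159), Lrg1 (24.1 to 6.67 FPKM, −1.72, adjusted p = 0.00381) and the interferon-response genes given below. Cts7 and Gm42047, which that rule leaves out by FPKM and by symbol, fell by −1.92 and −3.55.

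Decidual stromal genes were lower as a group at day 6.5. Of 28 tested, 12 fell, 1 rose and 15 did not pass, and adjusted over the list alone 14 were lower and 2 higher. The median was −0.52 (camera adjusted p = 1.57e-05, and adjusted p = 0.0902 with an estimated correlation). Angpt4, a ligand of the Tie2 receptor, fell by a log2 fold change of −1.66 (adjusted p = 0.000857), Bmp8a by −0.87 (adjusted p = 0.00159) and Wnt6 by −0.84 (adjusted p = 0.00571). The transcription factor genes Hand2 (−0.46, adjusted p = 0.114) and Hoxa10 (0.28, adjusted p = 0.089) and the progesterone receptor gene Pgr (−0.11, adjusted p = 0.609) did not pass. In the list of progesterone receptor and hedgehog targets 3 of 16 fell (Sgk1, Bmp2 and Gata2), with 1 higher and 6 lower adjusted over the list alone, and the list did not pass (median −0.02, camera adjusted p = 0.402). Wnt and BMP genes had 3 higher and 8 lower of 24, 4 and 9 adjusted over the list alone, with a median of −0.31 (camera adjusted p = 0.0139, and adjusted p = 0.385 with an estimated correlation), and −0.13 without D6.5 DTA replicate 1. Among them Rspo3, which raises Wnt signalling, fell by −1.06 (adjusted p = 0.000253). Of the secreted Wnt antagonists, Sfrp5 fell from 577 to 234 FPKM (−1.32, adjusted p = 0.00113) and Sfrp4 rose from 15.2 to 71.7 FPKM (2.24, adjusted p = 0.000433).

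**Figure D2:**
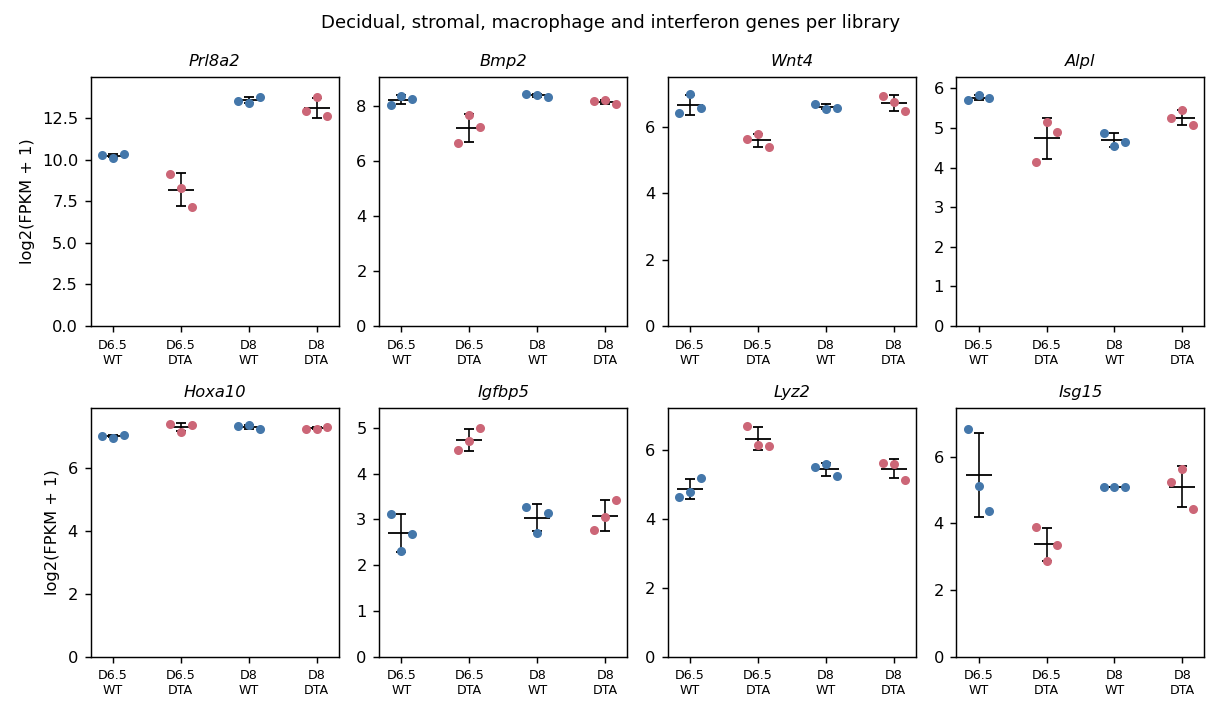
Expression of Prl8a2, Bmp2, Wnt4, Alpl, Hoxa10, Igfbp5, Lyz2 and Isg15 as log2(FPKM + 1) in each of the 12 libraries, with points for libraries and bars for the mean ± SD of the 3 libraries of a group. Prl8a2 averaged 1218 FPKM in D6.5 WT and 339.5 in D6.5 DTA, and 12300 FPKM in D8 WT and 9401 in D8 DTA.

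Endothelial genes were lower at day 6.5, with 5 of 25 lower and none higher, and 10 lower adjusted over the list alone. The median was −0.45 (camera adjusted p = 2.87e-06, and adjusted p = 0.385 with an estimated correlation). The junction gene Cldn5 fell by −1.32 (adjusted p = 0.0119), Notch4 by −0.86 (adjusted p = 0.00945), Plvap by −0.87 (adjusted p = 0.0319) and Eng by −0.84 (adjusted p = 0.03). Kdr, a receptor for vascular endothelial growth factor, did not pass (−0.45, adjusted p = 0.33). The list means per library were 2.885 in D6.5 DTA replicate 1, 3.532 and 3.41 in the other DTA libraries, and 3.684 to 3.819 in WT. Without D6.5 DTA replicate 1 the median was −0.27 and the list still passed (camera adjusted p = 0.000103). Of 20 angiogenic factors 1 rose and 3 fell, 2 and 4 adjusted over the list alone, and the list did not pass (median −0.22, camera adjusted p = 0.208). Cxcl12 rose (1.09, adjusted p = 0.0043), Angpt2 fell (−0.97, adjusted p = 0.00432) and Vegfa did not pass (−0.25, adjusted p = 0.427).

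Immune lists moved apart at day 6.5. Of 17 genes of macrophages and antigen presentation, 10 rose and none fell, 11 and none adjusted over the list alone, with a median of 0.46 (camera adjusted p = 9.47e-08, and adjusted p = 0.132 with an estimated correlation). The lysozyme gene Lyz2 rose from 28.5 to 80.6 FPKM (log2 fold change 1.46, adjusted p = 0.00195), and the complement genes C1qa, C1qb and C1qc rose by 0.69, 0.79 and 0.85 (adjusted p = 0.00478, 0.00404 and 0.00317). Of 18 natural killer genes 5 fell and none rose, 7 lower and 1 higher adjusted over the list alone, with a median of −0.34 (camera adjusted p = 0.04, and adjusted p = 0.516 with an estimated correlation). The perforin gene Prf1 fell by −0.87 (adjusted p = 0.0142), and the granzyme genes Gzmd, Gzme and Gzmf by −1.36, −1.53 and −1.71 (adjusted p = 0.0217, 0.016 and 0.0156). None of 5 neutrophil genes passed (median −0.47, camera adjusted p = 0.331).

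Interferon-response genes had the lowest list median at day 6.5 in the main fit. The giant cell trophoblast list, whose median was not settled, had a lower mean log2 fold change (−1.319 against −1.117). Of 21 tested 14 fell and none rose, 17 and none adjusted over the list alone, with a median of −1.21 (camera adjusted p = 2.92e-10, and adjusted p = 0.385 with an estimated correlation of 0.833). Isg15 fell from 55.5 ± 50.4 to 9.73 ± 3.74 FPKM (log2 fold change −2.08, adjusted p = 0.0293), Ifit1 from 10.1 to 1.33 FPKM (−1.83, adjusted p = 0.0432), Oasl2 from 17.9 to 3.67 FPKM (−1.74, adjusted p = 0.0262) and the transcription factor gene Stat1 by −1.05 (adjusted p = 0.00279). The WT libraries differed, with list means of 4.401, 3.312 and 2.884 against 2.347 to 2.541 in DTA. Of 5 inflammatory cytokine genes Icam1 fell (−0.75, adjusted p = 0.0404), 4 were lower adjusted over the list alone, and the median was −0.37 (camera adjusted p = 0.04, and adjusted p = 0.385 with an estimated correlation).

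Of 14 genes of uterine epithelium and glands 1 rose at day 6.5, Krt7 (0.80, adjusted p = 0.0146), with 4 higher adjusted over the list alone and a median of 0.48 (camera adjusted p = 0.04, and adjusted p = 0.385 with an estimated correlation). Without D6.5 DTA replicate 1, whose list mean was 4.212 against 3.683 and 3.698 in the other DTA libraries, that median was 0.258 and the list did not pass. Slc2a1, a glucose transporter, fell from 284 to 162 FPKM (−0.81, adjusted p = 0.00583). It was 1 of 3 glycolysis and hypoxia genes of 20 that fell (1 higher and 4 lower adjusted over the list alone, median −0.12, camera adjusted p = 0.0952). Of 9 steroid genes 1 rose and 4 fell, the same adjusted over the list alone (median −0.55, camera adjusted p = 0.0868), with Srd5a1 at −1.10 and Hsd11b2 at 1.10 (adjusted p = 0.00644 and 0.0112). Of 12 insulin-like growth factor genes 2 rose, the same adjusted over the list alone (median 0.03, camera adjusted p = 0.211). These were Igfbp5, from 5.69 to 26 FPKM (2.04, adjusted p = 0.00082), and Igf1 (1.22, adjusted p = 0.00816).

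Of 17 p53 and apoptosis genes 2 rose at day 6.5, 5 higher and 2 lower adjusted over the list alone (median 0.13, camera adjusted p = 0.0882), led by Pmaip1, which promotes cell death, from 4.64 to 17.9 FPKM (1.71, adjusted p = 0.00144). Of 27 extracellular matrix genes 2 rose and 3 fell, 6 and 5 adjusted over the list alone (median 0.23, camera adjusted p = 0.443). Lum rose (2.05, adjusted p = 0.0075), and Eln (−1.32, adjusted p = 0.00317) and Col1a1 (1034 to 529 FPKM, adjusted p = 0.0255) fell. Of 13 retinoic acid genes 3 rose and 2 fell, 3 and 4 adjusted over the list alone, with a median of −0.09, a mean of 0.02 and a camera adjusted p of 0.943. Cyp26b1, which breaks down retinoic acid, rose by 0.94 (adjusted p = 0.00702). Of 23 proliferation genes 2 fell, Rrm2 and Ccnd3, the same adjusted over the list alone (median 0.01, camera adjusted p = 0.861). None of the tested members passed in the lists of the unfolded protein response (18 genes, median −0.16, camera adjusted p = 0.0827), myometrium (8 genes, median 0.01, mean −0.01, camera adjusted p = 0.924) and mitochondrially encoded genes (12 genes, median −0.31, camera adjusted p = 0.197).

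The counts at day 6.5 depended on which libraries were fitted: 144 higher and 267 lower with only the day 6.5 libraries, 90 and 262 without replicate 3 of all groups, 75 and 108 without replicate 1, 30 and 22 without replicate 2, 232 and 375, 166 and 228, or 164 and 310 without WT replicate 1, 2 or 3, 831 higher without DTA replicate 2, 277 higher without DTA replicate 3 and 475 lower without D8 WT replicate 2. The calls of Igkc, Igha, Mmp7, Ighm, Isg15, Ifit1, Oasl2, Spink1, Bmp2, Gata2, Cldn5, Eng, Plvap, Prf1, Gzmd, Gzme, Gzmf, Icam1, Krt7, Rrm2, Ccnd3 and Col1a1 ended without at least 1 of the 12 libraries, and those of the natural killer, other trophoblast, inflammatory and Wnt lists without D6.5 DTA replicate 3. The call of the inflammatory list also ended without D6.5 WT replicate 1, and that of the epithelium list without D6.5 WT replicate 3 or D8 DTA replicate 3. The tallies of lists that follow leave out the estimated correlation, with which no list passed at day 6.5. Over 30 alternatives the calls of the epithelium, inflammatory, natural killer, other trophoblast, Wnt and giant cell lists were lost in 13, 8, 6, 6, 3 and 1. That of Prl8a2 was lost in 4 of 30, without a filter, with only the day 6.5 libraries, and without replicate 2 (adjusted p = 0.103) or 3 of all groups, and that of Wnt4 in 1, without replicate 2 of all groups (adjusted p = 0.0658).

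At day 8 the question was the same. Limma called 150 genes, against 1154 at day 6.5. With array weights, whose estimation stopped before it converged, it called 2429 at day 8 and 2335 at day 6.5. In every other alternative it called fewer genes at day 8, such as 75 against 411 with only the groups compared. The counts were not compared by a test. Prl3d1 and Cts7 were again lower, and the mast cell tryptase gene Tpsab1 was higher. Tpsab1 (ENSMUSG00000024173.11, chromosome 17: 25343245-25345562) rose from 0.747 ± 0.215 FPKM in WT to 20.8 ± 8.98 FPKM in DTA (n = 3 each, log2 fold change 3.55, adjusted p = 2.21e-05). Prl8a2, Bmp2 and Wnt4, which had fallen at day 6.5, did not pass: Prl8a2 averaged 12300 FPKM in WT and 9401 in DTA (−0.46, adjusted p = 0.739), Bmp2 had a log2 fold change of −0.24 (adjusted p = 0.716) and Wnt4 of 0.12 (adjusted p = 0.857). Of 12963 genes tested, 45 were higher and 105 lower in DTA, with 19 and 38 changed at least 2-fold.

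Among the largest changes at day 8, the pseudogenes Atp6v0c-ps2 and Vcp-rs rose again, from 2.96 to 64.0 FPKM and from 3.28 to 58.2 FPKM (log2 fold changes 4.03 and 3.76, adjusted p = 0.000107 and 1.62e-05). Pmaip1 rose from 13.2 to 40.6 FPKM (1.54, adjusted p = 0.0052). Next among rises by the naming rule, at 1.05 to 1.12, were Tacstd2, Ear1, a ribonuclease gene of eosinophils, C1qtnf12 and Sct, the secretin gene (adjusted p = 0.0257, 0.00845, 0.0158 and 0.0389). Some called genes that the rule leaves out rose more, such as Gm10039 (3.32) and Ccl21a (1.88). By the naming rule, which asks for a mean of at least 5 FPKM in the higher group, the largest falls besides Prl3d1, Cts7 and Psg22 were as follows. They were in Ldhd, a D-lactate dehydrogenase gene, from 41.9 to 10.1 FPKM (−2.06, adjusted p = 0.00243), Ceacam15 (−2.01, adjusted p = 0.0486) and Ngfr, a neurotrophin receptor gene (−1.89, adjusted p = 0.0117). Dppa1 and Creb3l3 followed (−1.79 and −1.54, adjusted p = 0.00366 and 0.00684). Below that limit, Pfpl and Psg29 fell by −2.41 and −2.38.

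Neutrophil genes were lower as a list at day 8 by camera. Of 5 neutrophil genes 1 fell, Mmp9, from 3.65 to 0.133 FPKM (log2 fold change −1.99, adjusted p = 0.00121), with 3 lower adjusted over the list alone and a median of −0.79 (camera adjusted p = 0.000544, and adjusted p = 0.194 with an estimated correlation). None of 18 natural killer genes passed alone, Prf1 among them (−0.44, adjusted p = 0.331), with a median of −0.35 (camera adjusted p = 0.000388, and adjusted p = 0.482 with an estimated correlation). None of 23 proliferation genes passed alone, with a median of 0.21 (camera adjusted p = 0.000388, and adjusted p = 0.762 with an estimated correlation). None of 18 genes of the list unfolded protein and stress response passed alone, with a median of −0.19 (camera adjusted p = 0.00694, and adjusted p = 0.724 with an estimated correlation). D8 DTA replicate 3 stood apart in these lists: its list means were 3.897 for natural killer genes against 4.513 and 4.345 in the other DTA libraries, and 4.977 for proliferation genes against 4.671 and 4.52. Without that library the medians were −0.252 for natural killer genes and 0.091 for proliferation, and neither these lists nor the unfolded protein list passed. The neutrophil median was −0.40 without it (camera adjusted p = 0.0326) and −1.20 without D8 DTA replicate 2, where that of proliferation was 0.34.

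Of 13 retinoic acid genes 1 rose at day 8, the retinol-binding gene Rbp1, from 6.93 to 12.6 FPKM (0.76, adjusted p = 0.0139), with 4 higher adjusted over the list alone and a median of 0.08 (camera adjusted p = 0.0165, and adjusted p = 0.225 with an estimated correlation), and of 0.15 or 0.12 without D8 DTA replicate 2 or 3. Slc2a1 rose from 156 to 246 FPKM (0.66, adjusted p = 0.0486), Id3 rose (0.54, adjusted p = 0.017), and H19, an imprinted RNA gene, fell from 28.8 to 15.4 FPKM (−0.86, adjusted p = 0.017). Of 28 decidual stromal genes 2 fell, Il11ra1 (−0.92, adjusted p = 0.0102) and Bmp8a (−0.53, adjusted p = 0.0492), with 1 higher and 2 lower adjusted over the list alone (median −0.05, camera adjusted p = 0.626). The endothelium list, with Kdr at −0.18 (adjusted p = 0.868), the macrophage list and the interferon list had no called member and medians of −0.10, −0.05 and −0.10 (camera adjusted p = 0.481, 0.953 and 0.579). Hand2 (−0.09), Hoxa10 (−0.04), Pgr (−0.07) and Vegfa (0.01) did not pass, with adjusted p-values of 0.893, 0.932, 0.88 and 0.994.

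**Figure D3:**
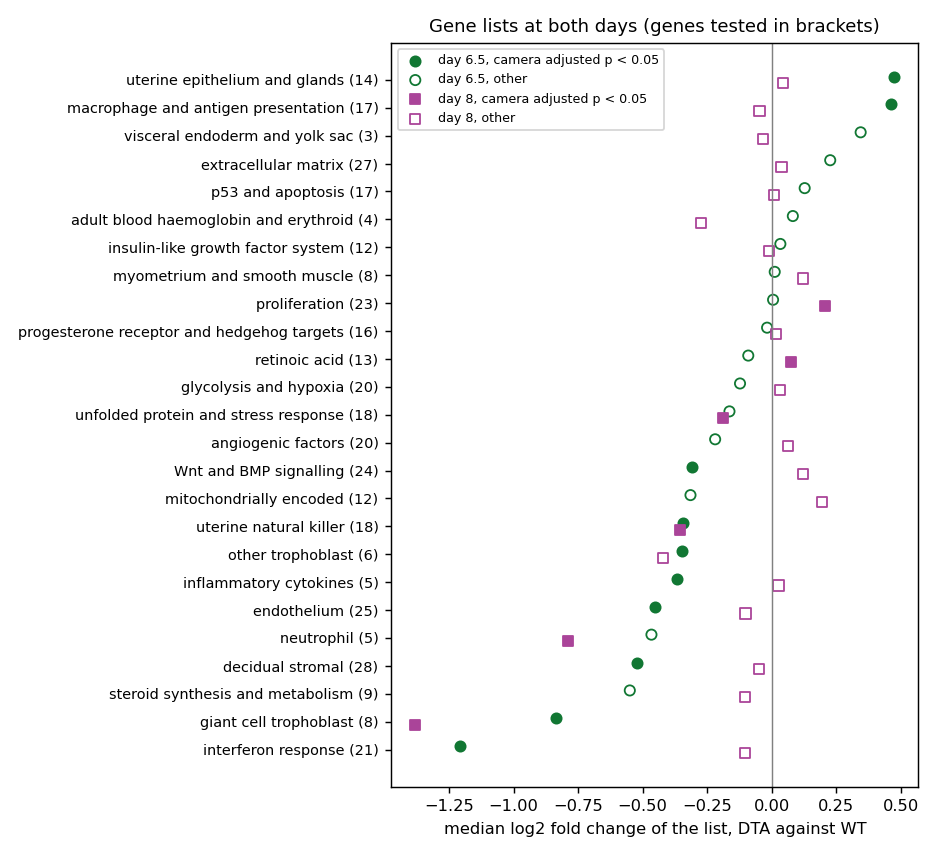
Median log2 fold change, DTA against WT, of the tested members of 25 gene lists at day 6.5 (circles) and day 8 (squares), with filled symbols for lists past a camera adjusted p of 0.05. At day 6.5 the medians ran from −1.21 for interferon response to 0.48 for uterine epithelium and glands, and at day 8 the lowest was −1.38 for giant cell trophoblast.

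The counts at day 8 were 12 higher and 22 lower without replicate 3 of all groups, 8 and 9 without replicate 1, 4 and 15 without replicate 2, 26 and 49 with only the day 8 libraries, 17 and 25, 12 and 27, or 15 and 34 without WT replicate 1, 2 or 3, 29 and 58 without DTA replicate 1, 203 lower without DTA replicate 2, 101 and 206 without D6.5 DTA replicate 1 and 69 lower without D6.5 WT replicate 3. The calls of Prl3d2, Bmp8a, C1qtnf12, Ceacam15, Ear1, H19, Id3, Il11ra1, Ngfr, Rbp1, Sct, Slc2a1 and Tacstd2 ended without at least 1 of the 12 libraries. The tallies of lists that follow leave out the estimated correlation, with which no list passed at day 8. Over 29 alternatives the call of the neutrophil list was lost in 3, and over 30 those of the natural killer, giant cell, proliferation, unfolded protein and retinoic acid lists in 3, 2, 2, 2 and 1. That of Prl3d1 was lost without replicate 3 of all groups (adjusted p = 0.051).

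The difference of the DTA effect between days asked which changes depended on the day. By camera the DTA effect on macrophage genes was lower at day 8 than at day 6.5, and that on interferon, decidual and endothelial genes was higher, with no single endothelial gene called. With an estimated correlation none of these 4 lists passed (adjusted p = 0.099, 0.506, 0.099 and 0.508). Of 12963 genes, 113 had a higher DTA effect at day 8 and 66 a lower one. Wnt4 differed by a log2 fold change of 1.18 (adjusted p = 0.0353). The largest positive differences were in Tpsab1 (3.45, adjusted p = 0.00318), the retinoic acid-binding gene Crabp1 (2.31, adjusted p = 0.025), the steroid enzyme gene Hsd3b6 (2.30, adjusted p = 0.0442), Gpr50 (2.13, adjusted p = 0.00525) and Coch (2.05, adjusted p = 0.0294). The largest negative differences were in Igkv5-39 (−3.17, adjusted p = 0.00729), Jchain (−3.05, adjusted p = 0.00847), Igkv8-21 (−2.98, adjusted p = 0.0333), Sfrp4 (−2.67, adjusted p = 0.00489) and Igkv3-2 (−2.43, adjusted p = 0.0485).

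Of the 25 lists 9 differed between days by camera, and none held with an estimated correlation. The interferon list shifted up by a median of 1.11 (camera adjusted p = 1.04e-08, and adjusted p = 0.506 with an estimated correlation), with 2 of 21 genes called and 13 adjusted over the list alone. Macrophage genes shifted down by −0.51 (camera adjusted p = 1.22e-08, and adjusted p = 0.099 with an estimated correlation), with 1 of 17 called and 10 adjusted over the list alone. The shifts were 0.37 for decidual stroma (5 of 28 called, 10 higher and 2 lower adjusted over the list alone), 0.39 for endothelium (none of 25) and 0.43 for Wnt and BMP genes (4 higher and 1 lower of 24, 11 and 3 adjusted over the list alone). Their camera adjusted p-values were 0.000293, 0.000223 and 0.000496, and with an estimated correlation the adjusted p-values were 0.099, 0.508 and 0.506. The other shifts were 0.42 for inflammatory cytokines, 0.24 for proliferation, 0.15 for glycolysis and hypoxia and 0.45 for mitochondrially encoded genes. Their adjusted p-values were 0.0408, 0.0298, 0.0408 and 0.0408, and 0.506, 0.63, 0.612 and 0.63 with an estimated correlation. In the same order these calls were lost in 13, 8, 9 and 10 of 29 alternatives, each without at least 1 of the 12 libraries.

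Across the 12963 genes, which are not independent replicates, the log2 fold changes of both days correlated with a Pearson r of 0.311 and a Spearman rho of 0.283. The days share no libraries. Genes called at both days numbered 65. Of these 18 were higher at both days, against 1.51 for independent lists, 42 were lower at both, against 5.82, and 5 changed in opposite directions. Both tests used the same variance per gene from all 12 libraries, so the lists were not independent. The numbers for independent lists may thus be too low. Of the 1154 genes called at day 6.5, 71.3% had the same sign at day 8.

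**Figure D4:**
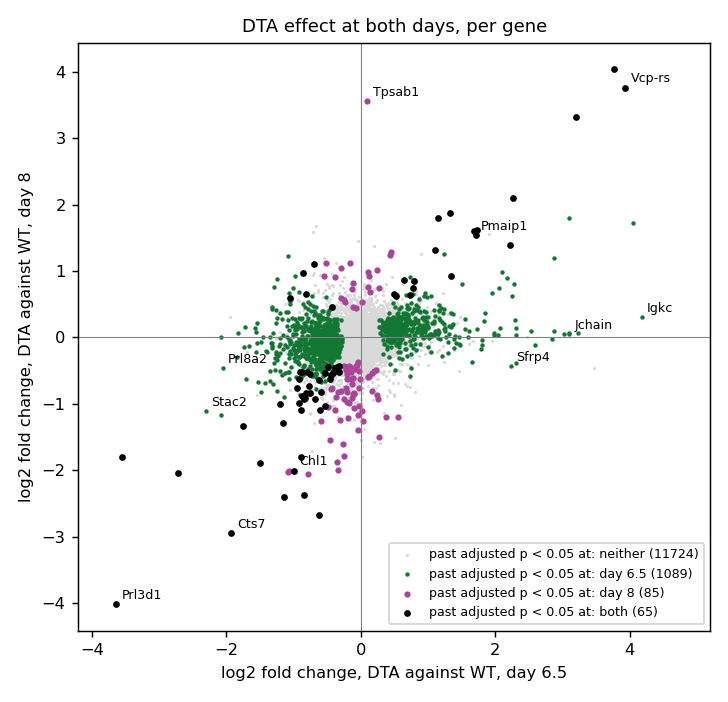
Log2 fold change of DTA against WT per gene at day 6.5 (horizontal axis) and day 8 (vertical axis) for 12963 genes, coloured by whether the gene passed an adjusted p of 0.05 at neither day (11724 genes), day 6.5 only (1089), day 8 only (85) or both (65). Prl3d1 lies at the lower left, at −3.63 and −4.01, and Vcp-rs at the upper right, at 3.94 and 3.76.

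The difference had 54 higher and 47 lower genes without D6.5 WT replicate 1, 30 and 27 without replicate 2, 35 and 15 without replicate 3, 31 and 11, 26 and 15, or 23 and 10 without D8 WT replicate 1, 2 or 3, 62 and 20 without D6.5 DTA replicate 3, 42 and 23 without D8 DTA replicate 1, and 214 and 116 without D6.5 DTA replicate 2. Without replicate 1, 2 or 3 of all groups limma called 0 genes, with 1131, 1228 and 1520 genes whose limma p was under 0.05 before adjustment. Fitted to all libraries, limma voom called 145. The calls of Wnt4, Coch, Crabp1, Hsd3b6, Igkv8-21 and Igkv3-2 ended without at least 1 of the 12 libraries, and that of Wnt4 in 14 of 29 alternatives. Without D6.5 DTA replicate 1 the list medians of the difference were 0.18 for endothelium, which still passed (camera adjusted p = 0.0116), and 0.21, 0.06 and 0.08 for inflammatory cytokines, proliferation and glycolysis and hypoxia, which did not. D6.5 DTA replicate 3 had a mean of 6.953 over mitochondrially encoded genes, against 8.584 and 8 in the other D6.5 DTA libraries. Without it that median was 0.15 and the list did not pass (camera adjusted p = 0.765), and that of glycolysis and hypoxia was 0.24. Without D6.5 DTA replicate 1 the mitochondrial median was 0.70 (camera adjusted p = 0.000702), and without D8 DTA replicate 3 that of proliferation was 0.11 and did not pass.

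The change from day 6.5 to day 8 in WT decidua gave a background for these effects. By camera the lists of decidual, natural killer and neutrophil genes were higher at day 8 and that of proliferation genes was lower. With an estimated correlation none passed (adjusted p = 0.248, 0.543, 0.248 and 0.624). Prl8a2 rose from 1218 to 12300 FPKM (log2 fold change 3.33, adjusted p = 0.000129), and Prf1 from 12.8 to 47.7 FPKM (1.82, adjusted p = 2.25e-05). The serine protease gene Htra1 rose by 3.58 (adjusted p = 4.44e-06). Of 12963 genes 2111 were higher and 1577 lower at day 8, and in DTA decidua 2320 were higher and 1669 lower. Scaling each library to the same sum (TPM) shifted the median of all genes by −0.258 in WT and −0.281 in DTA, and the share of higher genes among calls went from 57.2% to 24.2% and from 58.2% to 23.2%. The shares were 27.8% and 26.2% with limma voom, and 47.8% and 47.9% under quantile normalization.

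The largest rises in WT were in Pdzk1ip1 (1.31 to 86.1 FPKM, log2 fold change 5.26), Bco1, a carotene-cleaving enzyme gene (1.82 to 95.1 FPKM, 5.09), Gpnmb (4.92), Sprr2g (4.88), Aif1l (4.49) and Tmem238l (4.36). The largest falls were in the uterine gland protease genes Prss28 (106 to 3.06 FPKM, −4.18) and Prss29 (105 to 6.73 FPKM, −3.46), Hamp, the hepcidin gene (15.2 to 0.0767 FPKM, −3.89), Hsd3b6 (77.7 to 7.21 FPKM, −3.30), Arg2 (−3.13) and Col8a2 (−2.96). Decidual stroma had 13 higher and 3 lower genes of 28, 14 and 3 adjusted over the list alone, with a median of 0.38 (camera adjusted p = 0.00484, and adjusted p = 0.248 with an estimated correlation). Natural killer genes had 12 higher of 18, the same adjusted over the list alone, with a median of 1.09 (camera adjusted p = 0.000184, and adjusted p = 0.543 with an estimated correlation). Neutrophil genes had 4 higher of 5, 5 adjusted over the list alone, with S100a8 at 3.18 and a median of 1.73 (camera adjusted p = 0.000665, and adjusted p = 0.248 with an estimated correlation).

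Proliferation genes had 13 lower and 1 higher of 23 in WT, 19 and 1 adjusted over the list alone, with Cdk1 at −0.68 and a median of −0.54 (camera adjusted p = 3.86e-05, and adjusted p = 0.624 with an estimated correlation). Genes of the unfolded protein response had 6 higher and 1 lower of 18, 7 and 1 adjusted over the list alone, with Dnajb9 at 1.45 and a median of 0.28 (camera adjusted p = 0.0348, and adjusted p = 0.624 with an estimated correlation). The call of this list was lost in 6 of 30 alternatives, among them without D6.5 WT replicate 1 or 3 and without D8 WT replicate 1 or 2. Its median was 0.02 with TPM, where it passed (camera adjusted p = 0.0116). The decidual list did not pass under quantile normalization (median 0.26, camera adjusted p = 0.0781), nor the neutrophil list without a filter (camera adjusted p = 0.0645). In WT the counts were 3321 higher and 2950 lower with only the 2 WT groups fitted, 1183 and 801 without replicate 1 of all groups, 972 and 480 without replicate 2, 992 lower without D6.5 WT replicate 1, 1009 lower without D6.5 WT replicate 3 and 946 lower without D8 WT replicate 2, and in DTA 1005 and 984 were lower without D8 DTA replicate 1 or 2.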

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

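All tests in this part except the tests of the difference between days were chosen after the results they weigh were seen. No group had enough libraries for a test of single libraries that lie far from the rest. What drew attention here was a DTA effect that differed between day 6.5 and day 8 by a limma test of the difference itself, in 113 genes with a higher effect at day 8, 66 with a lower one, and 9 lists, none of which passed with an estimated correlation (lowest adjusted p = 0.099).

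The list medians of the difference were 0.3738 for decidual stroma, 0.3912 for endothelium, −0.5105 for macrophages and antigen presentation, 1.105 for interferon response, 0.4228 for inflammatory cytokines, 0.235 for proliferation, 0.1479 for glycolysis and hypoxia, 0.4315 for Wnt and BMP genes and 0.445 for mitochondrially encoded genes. Among named genes the DTA effect was higher at day 8 in Alpl (1.606), Angpt4 (1.531), C1qtnf12 (1.807), Coch (2.051), Crabp1 (2.314), Ear1 (1.27), Gpr50 (2.127), Hsd3b6 (2.302), Il11 (1.135), Irf7 (1.468), Lrg1 (1.877), Rspo3 (0.9657), Sfrp5 (1.745), Slc2a1 (1.472), Stat1 (1.002), Stra6 (1.471), Tacstd2 (1.638), Tpsab1 (3.455), Wnt4 (1.176) and Wnt6 (1.063). It was lower at day 8 in H19 (−1.111), Igfbp5 (−1.994), Igkv3-2 (−2.427), Igkv5-39 (−3.166), Igkv8-21 (−2.98), Jchain (−3.053), Lyz2 (−1.45), Mmp9 (−1.661), Prl5a1 (−1.338), Prl7a1 (−1.539), Psg22 (−2.047) and Sfrp4 (−2.665). Prl5a1, Prl7a1 and Psg22 averaged 0.21, 0.213 and 0.61 FPKM in D6.5 WT, against 2.05, 3.09 and 5.73 FPKM in D8 WT. With little room to fall at day 6.5 on the log2(FPKM + 1) scale, their differences do not show a stronger DTA effect at day 8.

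Other splits of the libraries were counted for each number of calls, with the real split included. For the difference between days 100 splits were drawn, and 1 of the 100, the real one, gave at least 179 genes, with 140 as the highest other. These splits mixed WT and DTA within each day, so they stand for no DTA effect at either day. They cannot tell whether a DTA effect equal at both days would give as many genes, so no conclusion was drawn for the difference. For its 9 lists 13 of the 100 splits gave as many, with 12 as the highest other, so chance was not excluded for the number of lists. The other comparisons have 10 splits, too few for a share under 0.05. Wherever lists were counted, splits other than the real one gave as many, so chance was not excluded for the number of lists there either. Of these 10 splits, 1 gave at least 1154 genes at day 6.5, with 0 as the highest other, and 2 gave at least 10 lists, with 10 as the highest other. At day 8, 1 gave at least 150 genes, with 0 as the highest other, and 4 gave at least 6 lists, with 9 as the highest other. Between days in WT, 1 gave at least 3688 genes, with 0 as the highest other, and 8 gave at least 5 lists, with 10 as the highest other. Between days in DTA, 1 gave at least 3989 genes, with 1572 as the highest other.

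Interferon-response genes were lower in D6.5 DTA than in D6.5 WT, with a list median of −1.21. A single WT library with high values as the whole explanation would leave a median near 0 without D6.5 WT replicate 1, and the median stayed at −0.847, with 10 rather than 14 of 21 genes lower and 19 of 21 below 0. Fewer macrophages as the source would lower the macrophage list as well, and its median was 0.4616, with 10 of 17 genes higher. The size of the change stays open, since the 3 WT libraries differed in this list, and so does a difference in interferon exposure between the pregnancies, which was not tested. With an estimated correlation of 0.833 between its genes the list did not pass (adjusted p = 0.385).

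Decidual stromal genes were lower in D6.5 DTA, with a list median of −0.52, a call lost with an estimated correlation (adjusted p = 0.0902). A lower share of decidual cells, with every other cell type up alike, would move macrophage and endothelium markers together, and they moved apart by 0.948 log2 units (pooled SD between libraries 0.205). A tissue at an earlier stage would move genes against the change from day 6.5 to day 8 in WT. The covariance of both changes across genes was −0.0234 against 0.017 simulated from the shared WT libraries alone, a difference of −0.0404, with a Pearson r of −0.116. The simulation drew noise for each gene on its own, so its SD (0.000602 over 100 simulations) leaves out shifts that genes share. That SD is therefore no measure of how far the difference could lie from 0 by chance. Of 474 genes called in both, 319 went opposite ways and 155 the same way, against 170 and 158 for independent lists. These lists are not independent, since they share the D6.5 WT libraries. Of the 3688 genes called between days in WT, 59.5% went opposite ways. By these directions alone, a delay of the decidua is a candidate explanation, found and tested on the same data. A change in which cell types took part stays open beside it.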

How the results depend on the processing

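The alternatives were chosen before the data were examined, except limma voom on reads rebuilt from FPKM, the replicate number as one block across both days, and the addition of Gt(ROSA)26Sor, Chl1, A2m and genes of chromosome 11, which were chosen after seeing the data. Over 30 alternatives the 374 log2 fold changes of named genes gave 11030 values. Of these, 10046 kept their side of the threshold, 826 were no longer past it, 155 came to be past it and 3 reversed. The 100 list medians, with the estimated correlation left out, gave 2963 values. Of these, 2793 kept their side, 98 were no longer past the threshold, 70 came to be past it and 2 reversed. A change of sign counted as reversed only where the value was past the threshold in the main fit or the alternative. Signs changed without a call in 58 gene values and 165 list values, which are among those that kept their side. The reversed genes were mt-Co1 (−0.386), mt-Nd2 (−0.60) and mt-Nd5 (−0.644) between days in WT under quantile normalization. The reversed list was visceral endoderm and yolk sac without a filter, at −0.0411 for day 6.5 and 0.0548 for the difference between days, where more of its members entered. In each fit that kept all libraries every gene called at day 6.5 or day 8 and tested there kept its direction.

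Numbers of calls moved as follows, and the causes were not tested. With an estimated correlation camera called 0 lists at day 6.5, 0 at day 8, 0 between days in WT and 0 for the difference. A filter of FPKM of at least 5, which left fewer genes to test, gave 238 higher at day 6.5 (a share of 26.2% of calls), 64 lower at day 8, 781 lower between days in DTA, 927 lower in WT and 16 lower for the difference. No filter gave 416 lower at day 6.5, 26 higher at day 8 and 42 higher and 38 lower for the difference. Array weights, whose estimation stopped before it converged, gave 897 higher and 1438 lower at day 6.5, 1026 and 1403 at day 8, 856 and 584 for the difference, 4077 and 4016 between days in WT and 2701 lower in DTA. Fits of only the groups compared gave 144 and 267 at day 6.5, 26 and 49 at day 8, 1251 and 607 between days in DTA and 3321 and 2950 in WT. Scaling each library to the same sum (TPM) gave 24 higher at day 8, 56 and 35 for the difference, 1275 and 4232 between days in DTA, and 1138 and 3561 with 8 lists in WT. A pseudocount of 0.1 gave 65 lower at day 8 and 35 lower for the difference, and a pseudocount of 5 gave 165 lower at day 8. Quantile normalization gave 3 lists between days in WT. A term for replicate 3 gave 71 and 43 for the difference. limma voom gave 691 higher at day 6.5 (53.9% of calls against 37.7%), an agreement of 0.424 between days, 4376 lower between days in DTA, and 3693 lower with 8 lists in WT, with median shifts of −0.234 and −0.216.

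The replicate number as a block was fitted as well. Deviations of libraries with the same number correlated at −0.0276, 0.0579 and 0.026 at day 6.5 and at 0.0945, −0.175 and −0.0899 at day 8, and not every library correlated best with its own number. Across days pairs with the same number ran from −0.0467 to 0.343 (replicate 3 of D6.5 DTA and D8 DTA) and other pairs from −0.393 to 0.302. Pairing by number was thus not shown, and a batch shared by replicate 3 was left open. The replicate block within each day gave 263 higher at day 6.5, 17 and 39 at day 8 and 24 and 15 for the difference. The replicate number as one block across both days gave 69 lower at day 8.

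Leaving out a library, or a replicate number of all groups, gave these ranges over 15 fits, with fewer libraries in each. Where a group kept 1 library less, its spread was pooled with the others. At day 6.5 there were 30 to 831 genes higher, 22 to 1043 lower and 5 to 12 lists. At day 8 there were 4 to 101 higher, 9 to 206 lower and 1 to 7 lists. The difference had 0 to 214 higher, 0 to 116 lower and 6 to 10 lists. In WT between days there were 972 to 2447 higher, 480 to 2027 lower and 4 to 7 lists, and in DTA 1029 to 2574 higher and 559 to 2221 lower. The agreement of both days ranged from 0.2485 to 0.3621. At the inferred totals of 31.25 M to 38.89 M, a value of 0.01 FPKM stands for less than 1 read in a gene of 1 kilobase, so genes near that level were not resolved.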

Other observations

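All tests in this part that weigh an explanation were chosen after the results they weigh were seen. In DTA decidua the change from day 6.5 to day 8 was described by the same lists, and its difference from the change in WT equals the difference of the DTA effect between days. Of 28 decidual stromal genes 18 rose in DTA and none fell, 19 adjusted over the list alone, with a median of 0.84 (camera adjusted p = 5.44e-07, and adjusted p = 0.0324 with an estimated correlation). Endothelial genes had 10 of 25 higher (median 0.28, camera adjusted p = 0.0023, and adjusted p = 0.621 with an estimated correlation). Interferon-response genes had 10 higher and 1 lower of 21 (median 0.95, camera adjusted p = 0.00228, and adjusted p = 0.633 with an estimated correlation). Macrophage genes had 13 lower and 2 higher of 17 (median −0.53, camera adjusted p = 0.000242, and adjusted p = 0.285 with an estimated correlation).

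The 5 genes called at both days in opposite directions fell in DTA at day 6.5 and rose at day 8, and Cadm4, Cryl1 and Tm6sf2 are named after their values were seen. The log2 fold changes at day 6.5 and day 8 were −0.81 and 0.66 for Slc2a1, −0.70 and 1.11 for C1qtnf12, −0.86 and 0.97 for Cadm4, −0.43 and 0.45 for Cryl1, and −1.05 and 0.60 for Tm6sf2. In WT all 5 were lower at day 8 than at day 6.5, as Slc2a1 was with 284 and 156 FPKM (limma adjusted p = 0.000759).

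Of the 65 genes called at both days, 60 changed the same way, and they lay on chromosome 11 more often than tested genes. On that chromosome lay 17 of the 60, against 5.04 for genes picked at random, an odds ratio of 4.37 (Fisher's exact test, adjusted p = 0.000108 over 20 chromosomes). Of the 1174 genes called at a single day 8.77% lay there, and 8.39% of all tested genes. The 17 genes that changed the same way there lay between positions 16635109 and 120764419, so they were not confined to 1 short stretch. An allele or segment of another strain on chromosome 11 in the DTA mice is a candidate explanation, found by looking over all chromosomes. Alleles linked to Rosa26 on chromosome 6 could add to it, but the 3 genes within 20 Mb of Rosa26, against 0.903 picked at random, left this open (odds ratio 3.48, 95% interval 0.692 to 10.9, Fisher's exact p = 0.0615).

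Some genes there were looked at after their values were seen. The transcript of the Rosa26 locus, Gt(ROSA)26Sor (chromosome 6: 113067428-113077333), was listed at 0.30, 1.71 and 4.06 FPKM in the D6.5 DTA libraries, with 4.53 ± 0.348 FPKM in D6.5 WT. It was listed at 0.24, 0.06 and 0.14 FPKM in D8 DTA, with 3.65 ± 0.234 FPKM in D8 WT. Decidua is maternal, so these low values in D8 DTA show that the maternal tissue itself differed from WT at this locus. The D6.5 DTA libraries also differed among themselves there. The mothers' genotype was not in the labels, so whether it gave these differences, and the one between days, was left open. How much of each DTA effect belongs to the ablation was left open with it. Without D6.5 DTA replicate 3, the library at 4.06 FPKM, 277 genes were higher and 659 lower at day 6.5. Near the locus, Chl1 had log2 fold changes of −0.996 and −2.004 at day 6.5 and day 8, and A2m of −1.164 and −1.28.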
